A study of Drosophila melanogaster with 12 samples.

How the data were processed

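Brains of male flies from 4 groups were compared by RNA sequencing, with 3 libraries per group. Per the labels' protocols, a daughterless-GeneSwitch driver, which acts when flies eat RU486, drove a hairpin against Atx2 (stock 44012) or a control hairpin against mCherry (stock 35785), with or without a TDP-43 transgene. Male progeny were collected 1 to 2 days after eclosion from crosses kept at 25 °C, and brains were taken after 6 days on RU486. A stranded polyA kit and paired reads of 150 bases were used, with 40 M reads planned per library. The labels give 3 biological replicates per group and no batch or date. The adjusted p-values measure the spread between libraries as so labelled.

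The authors deposited a single table of raw read counts per gene, with whole numbers and no normalisation. The submitters' processing notes name Trim Galore, STAR 2.7.3a, SAMtools and DESeq2, and the genome build dm6. How reads were assigned to genes, including the strand setting and the treatment of reads that match several genes, is not given in the sources used here. Values of overlapping or antisense genes, and of near-identical copies within gene families, are therefore uncertain as to which gene the reads came from. All 12 columns of counts belonged to a labelled library, and 0 columns belonged to none. Of 17562 gene symbols in the table, 17488 were matched to a FlyBase identifier, 641 of them by an older symbol, and 74 were not matched. Coordinates are those of dm6, chromosome first, then start and end.

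Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr on the 4 groups, which left 10738 genes and removed 6824. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.962 to 1.03. One model with a mean for each of the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom, and tested with the robust quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called below an adjusted p of 0.05 with no minimum fold. The p-values written as "edgeR adjusted p" come from this test and adjustment. Levels are CPM, counts relative to the library's scaled total, computed from the deposited counts and the scaled library sizes, as mean ± SD over n = 3 libraries. Fold changes are on the log2 scale ± the standard error.

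The comparisons were TDP-43 against control with mCherry RNAi, Atx2 RNAi against mCherry RNAi with TDP-43, the same without TDP-43, TDP-43 against control with Atx2 RNAi, and the interaction of TDP-43 with the hairpin. A description of opposite calls in the first and second comparison was added, because the series title speaks of a rescue. Both of those comparisons use the same TDP-43 libraries with opposite sign, so libraries were simulated with no effects, with a TDP-43 effect only, and with an equal TDP-43 effect under both hairpins, 20 times each. The spread of the simulated counts was set after a first version called too few genes, and the simulations with an equal effect then called a mean of 3605 genes in the first comparison.

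The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. A gene can be named if it is called and its groups' libraries do not overlap in CPM, or, for the interaction, if it is called. From these come the 6 largest rises and 6 largest falls at 5 CPM or more in the higher group, and the 5 largest each way with a gene name at 20 CPM or more. Up to 4 called members per list, by smallest adjusted p, and up to 8 genes per direction among the opposite calls are added. The last 3 comparisons take 3 each way. Atx2, TBPH and the transgene markers w, v and y are given whether called or not, and 2 members of a list with no call may be given. Any other gene is said to have been chosen after its values were seen. Where a choice remained, genes whose call held with each library left out were preferred, and this preference was set after the data were seen. For genes at or under 3 counts per library in a group, which is 0.0665 to 0.103 CPM, levels are given and no fold. This floor covers counting error only.

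Gene lists, 40 in all, were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and 37 lists with 5 or more tested members entered the test. P-values were adjusted over the lists within a comparison. The count of called members is also given with the p-values adjusted over the list alone. Of the listed symbols, 9 had no entry in the table.

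Library totals ran from 29184618 to 45104293 counts, and 12227 to 13466 genes had a count in a library. The steps were tested on simulated data before use. In the simulated first comparison, run on 10592 genes, 59.1% of 66 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 86.4% of 66 changed 4-fold were called with the right sign. Of the calls there, 4.79% were unchanged genes. In the simulated interaction, 61.8% of the changed genes were called.

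Other settings tried were relative log expression scaling, the Wald test of DESeq2 1.42.0, no low-count filter, a minimum of 1 CPM in 3 libraries, the replicate number as a block, a test against a fold of 1.5, 1 surrogate variable from sva 3.50.0, each library left out, and only the 6 libraries of a comparison. The list tests were repeated with an estimated correlation, with fry and with the block. Alternatives added after seeing the data were an eye-transcript score as a covariate, leaving out the 3 libraries with over 1000 CPM of ninaE, the block within the 6 libraries of a comparison, and the TDP-43 libraries with mCherry RNAi divided so that the first and second comparison share none.

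Whether replicate numbers pair libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. Between the TDP-43 groups with mCherry and with Atx2 RNAi the correlations were 0.252, 0.623 and 0.193. Between the Atx2 RNAi groups without and with TDP-43 they were 0.291, 0.399 and 0.144. All lie over 0.1, the level set for treating numbers as pairs, so values with the block are given in these 2 comparisons where they change a call. The pairing comes from the data alone, since the labels do not say what a number shares. In the other comparisons the numbers did not pair the libraries. Sleep measurements, protein levels, alternative splicing and the transcript of the TDP-43 transgene itself were not analysed here.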

Results

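RNA was sequenced from brains of male flies in 4 groups of 3 libraries. Control flies and flies expressing TDP-43, an RNA-binding protein that aggregates in motor neuron disease, each carried either a hairpin against mCherry, which flies lack, or a hairpin against Atx2, the fly ataxin-2 gene. With mCherry RNAi, libraries held from 29755318 to 39912806 counts in control flies and from 32744607 to 45104293 in TDP-43 flies. With Atx2 RNAi they held from 29184618 to 43714499 counts in control flies and from 31726136 to 40792054 in TDP-43 flies. Levels are given below in CPM, counts scaled to a common library size, as mean ± SD over n = 3 libraries. The values after a level are the log2 fold change ± SE and the p-value of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

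Atx2 (3R, 15408423 to 15417277), the target of the hairpin, was lower in all 6 libraries with its hairpin than in all 6 with the mCherry hairpin. Its level was 350.3 ± 11.4 CPM in control flies with mCherry RNAi and 159.8 ± 7.17 CPM with Atx2 RNAi (-1.13 ± 0.06, edgeR adjusted p = 1.33e-06). In TDP-43 flies it was 287 ± 18.5 CPM with mCherry RNAi and 154 ± 9.29 CPM with Atx2 RNAi (-0.89 ± 0.06, edgeR adjusted p = 5.34e-06). Atx2 was also lower with TDP-43 than without it under the mCherry hairpin (-0.29 ± 0.06, edgeR adjusted p = 0.00245). TBPH (2R, 23859067 to 23862593), the fly gene for TDP-43, fell with TDP-43 expression from 136 ± 10.04 to 68.6 ± 2.99 CPM (-0.98 ± 0.06, edgeR adjusted p = 1.49e-07) with mCherry RNAi and from 141 ± 3.48 to 78.9 ± 2.2 CPM (-0.84 ± 0.06, edgeR adjusted p = 7.01e-07) with Atx2 RNAi. The transgene's transcript was not analysed. The eye pigment gene w (X, 2790599 to 2796466), which transgenes carry as a marker, stood at 10.5 ± 0.693, 2199 ± 194, 13.2 ± 1.65 and 2046 ± 53 CPM in control and TDP-43 flies with mCherry RNAi and in control and TDP-43 flies with Atx2 RNAi. The body colour gene y, another such marker, stood at 15.2 ± 6.36, 111 ± 14.6, 23.2 ± 9.12 and 63.8 ± 2.76 CPM in the same order (2.87 ± 0.36, edgeR adjusted p = 3.62e-04 with mCherry RNAi). The marker v stood at 11.9 ± 3.79, 24.2 ± 5.57, 8.93 ± 1.89 and 12.5 ± 3 CPM, and its call with mCherry RNAi (1.02 ± 0.27, edgeR adjusted p = 0.0154) was lost without replicate 1 of the control group (edgeR adjusted p = 0.0530) or replicate 3 of the TDP-43 group (0.0551). TDP-43 and control flies thus differed in marker transcripts too.

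**Figure D1:**
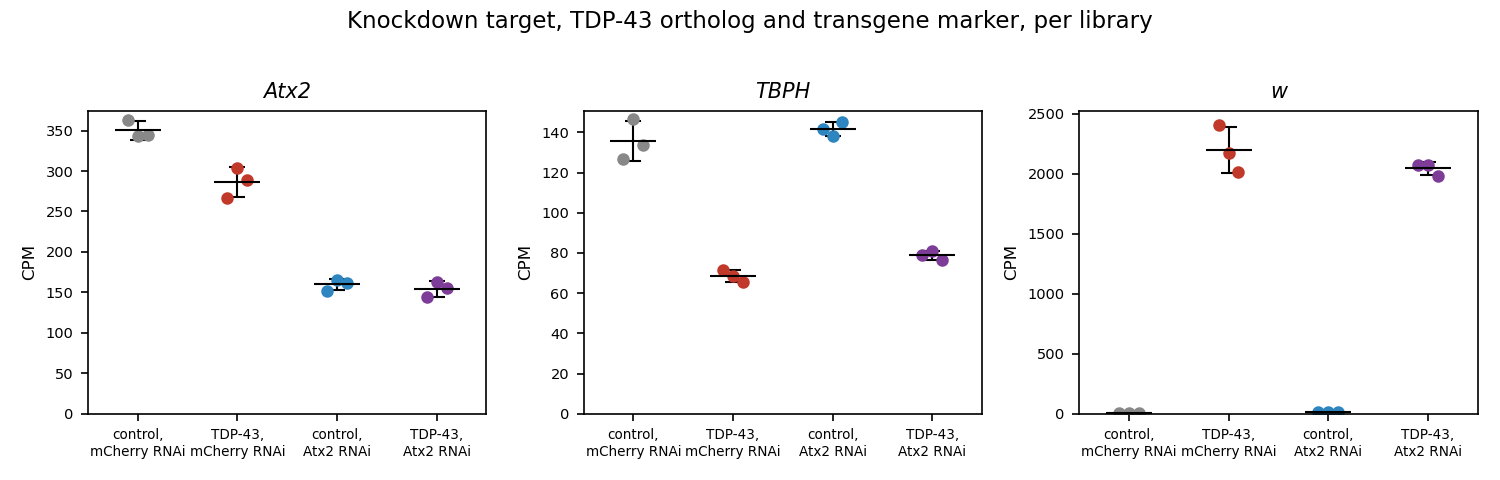
Level of Atx2, TBPH and w in CPM (vertical axes, from 0) in each library of the 4 groups (horizontal axes), with the mean ± SD (n = 3) of each group. Atx2 had means of 350.3 and 287 CPM with mCherry RNAi and of 159.8 and 154 CPM with Atx2 RNAi, and w had means of 2199 and 2046 CPM in the TDP-43 groups and of 10.5 and 13.2 CPM in the control groups.

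The first comparison asked what TDP-43 expression changes in the brain when the hairpin is the control. A difference in genetic background between flies with and without the transgene cannot be told apart from a TDP-43 effect here. Many genes changed, most by small amounts. Transcripts of the yolk proteins Yp1, Yp2 and Yp3, of the chaperone Hsp70Bb, of the autophagy kinase Atg1 and of the clock gene vri rose. Transcripts of the insulin-like peptides Ilp2 and Ilp3, of the peptide SIFa and of the synaptic genes Rbp and slo fell. By edgeR's test, 4035 of 10738 genes were called, 2067 higher and 1968 lower with TDP-43, and the median size of a called change was 0.44 on the log2 scale. Of the called genes, 1008 rose and 130 fell more than 2-fold. In 4987 genes, or 46.4%, the groups' libraries did not overlap, where chance gives 10%.

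The largest rises were in genes better known from the female fat body. Yp1 (X, 10053811 to 10055498), which encodes a yolk protein, rose from 1.63 ± 0.63 to 2398 ± 1458 CPM (10.55 ± 1.21, edgeR adjusted p = 2.68e-04). Yp2 rose from 1.49 ± 0.519 to 1212 ± 765 CPM (9.70 ± 1.08, edgeR adjusted p = 2.26e-04) and Yp3 from 1.43 ± 0.203 to 982 ± 585 CPM (9.41 ± 1.07, edgeR adjusted p = 2.55e-04). The fat body gene fit, which is female-biased, rose from 0.494 ± 0.292 to 65 ± 36.9 CPM (7.01 ± 0.93, edgeR adjusted p = 5.48e-04), along with asRNA:CR45046, which overlaps it. Lsp1beta (2L, 898500 to 901316), a storage protein gene of the larval fat body, fell instead, from 101 ± 47.7 to 1.48 ± 0.748 CPM (-6.13 ± 0.53, edgeR adjusted p = 4.39e-05). Of the fat body list, 9 rose and 2 fell of 20. Obp99a rose from 3.8 ± 0.316 to 57.1 ± 25.5 CPM (3.91 ± 0.45, edgeR adjusted p = 1.97e-04) and Obp99b fell from 22.4 ± 11.8 to 0.798 ± 0.364 CPM (-4.83 ± 1.10, edgeR adjusted p = 0.00917). The abundant fat body gene apolpp, chosen after its values were seen, stood at 1818 ± 725 and 2332 ± 1088 CPM and was not called (0.36 ± 0.39, edgeR adjusted p = 0.513). Among the other largest changes by fold, the calls of CG33346, CG8343, Obp83b and Os-C rested on few libraries. CG33346 was not called without replicate 2 of the TDP-43 group (edgeR adjusted p = 0.211) or without control replicate 1, 2 or 3 (edgeR adjusted p = 0.113, 0.119 and 0.119). CG8343 was not called without replicate 3 of the TDP-43 group (edgeR adjusted p = 0.0630) or without control replicate 1, 2 or 3 (edgeR adjusted p = 0.0848, 0.0788 and 0.0813). Obp83b was not called without control replicates 1 or 3 (edgeR adjusted p = 0.103 and 0.0676) or TDP-43 replicates 1, 2 or 3 (edgeR adjusted p = 0.108, 0.120 and 0.134). Os-C was not called without control replicate 1 (edgeR adjusted p = 0.0763) or TDP-43 replicates 1, 2 or 3 (edgeR adjusted p = 0.0892, 0.0763 and 0.102).

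Some genes were close to absent in TDP-43 flies. The receptor gene mthl8 (3L, 22428 to 26308) stood at 62.5 ± 3.41 CPM in control flies and at 0.0473 ± 0.082 CPM with TDP-43, below the level of 3 counts (edgeR adjusted p = 3.87e-07). The antisense RNA genes asRNA:CR45822 (3L, 7355717 to 7356598) and asRNA:CR45835 (3L, 7361639 to 7363598) stood at 8.78 ± 1.06 and 12.7 ± 1.31 CPM in control flies. With TDP-43 and mCherry RNAi they stood at 0.0166 ± 0.0148 and 0.0737 ± 0.0268 CPM (edgeR adjusted p = 1.70e-09 and 3.14e-10). TotX, a stress peptide gene, stood at 6 ± 5.38 CPM in control flies and 0.0674 ± 0.0519 CPM with TDP-43. GstD9 fell from 119 ± 3.04 to 25.2 ± 0.836 CPM (-2.24 ± 0.10, edgeR adjusted p = 2.50e-08) and Ugt35C1 from 30.8 ± 3.68 to 6.98 ± 0.969 CPM (-2.15 ± 0.14, edgeR adjusted p = 3.87e-07), both members of enzyme families that clear foreign compounds.

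Genes of protein quality control responded unevenly. Hsp70Bb, which encodes an inducible chaperone, rose from 153 ± 33.1 to 941 ± 100.3 CPM (2.62 ± 0.16, edgeR adjusted p = 2.10e-06) and Hsp70Ba from 16.5 ± 1.83 to 145 ± 30.0 CPM (3.13 ± 0.20, edgeR adjusted p = 2.64e-06), though these near-identical copies can share reads. Hsp67Ba fell (-0.64 ± 0.06, edgeR adjusted p = 7.96e-06). Of the heat shock and chaperone list, 4 rose and 5 fell of 22, or 5 and 5 adjusted over the list alone. Atg1, the kinase that starts autophagy, rose from 201 ± 7.75 to 648 ± 6.21 CPM (1.69 ± 0.05, edgeR adjusted p = 3.14e-10). The protease gene Cp1 rose from 213 ± 37.3 to 429 ± 85 CPM (1.01 ± 0.16, edgeR adjusted p = 9.75e-04) and cathD by 0.36 ± 0.05. Of the autophagy and lysosome list, 6 rose and 0 fell of 25. Of the unfolded protein and integrated stress response list, 10 rose and 3 fell of 23, or 12 and 3 adjusted over the list alone, among them Nmdmc (1.01 ± 0.15, edgeR adjusted p = 3.60e-04), Edem1 (0.33 ± 0.05, edgeR adjusted p = 6.02e-04) and Xbp1 (0.29 ± 0.05, edgeR adjusted p = 0.00119). Of the proteasome list, 9 rose and 0 fell of 35. Of the oxidative stress list, 4 rose and 1 fell of 24, or 1 and 1 adjusted over the list alone, with Gclm higher (0.68 ± 0.14, edgeR adjusted p = 0.00241) and Sod3 lower (-1.28 ± 0.18, edgeR adjusted p = 4.62e-04). Camera, which sets a list against the other genes, called none of these 5 lists, with adjusted p of 0.415 (heat shock), 0.172 (autophagy), 0.138 (unfolded protein), 0.138 (proteasome) and 0.487 (oxidative stress). The fry test, which asks whether a list moves on balance, called the autophagy, unfolded protein and proteasome lists higher (adjusted p = 5.58e-05, 0.00230 and 0.0249).

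Clock and sleep genes moved in both directions. The transcriptional repressor gene vri rose from 17.2 ± 2.89 to 71.9 ± 23.7 CPM (2.06 ± 0.27, edgeR adjusted p = 3.89e-04) and tim, which closes the clock's feedback loop, from 92.7 ± 13.2 to 175 ± 28.7 CPM (0.92 ± 0.13, edgeR adjusted p = 3.80e-04). The light receptor gene cry fell from 79.6 ± 8.85 to 53.5 ± 1.18 CPM (-0.57 ± 0.07, edgeR adjusted p = 7.06e-05) and nocte fell (-0.36 ± 0.06, edgeR adjusted p = 6.00e-04). Of the clock list, 3 rose and 6 fell of 18, with a median log2 fold change of -0.07, a mean of 0.28 and a set test pointing down (camera adjusted p = 0.569). The brains' hour of collection is not given in the sources used here. Dop2R, a dopamine receptor gene, rose from 96 ± 3.44 to 153 ± 3.8 CPM (0.67 ± 0.05, edgeR adjusted p = 8.11e-07) and Dop1R1 from 294 ± 18.1 to 505 ± 64.4 CPM (0.78 ± 0.09, edgeR adjusted p = 3.59e-05). Snap24 (-0.36 ± 0.05, edgeR adjusted p = 1.61e-04) and qvr (-0.31 ± 0.04, edgeR adjusted p = 1.89e-04), which encodes a sleep-promoting membrane protein, fell. Of the sleep list, 7 rose and 16 fell of 44, and its median was -0.05, its mean 0.01 and its test pointed down (camera adjusted p = 0.149).

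More neuropeptide genes fell than rose. Ilp3, which encodes an insulin-like peptide made in the brain, fell from 13.6 ± 1.44 to 2.39 ± 0.516 CPM (-2.51 ± 0.21, edgeR adjusted p = 4.78e-06) and Ilp2 from 196 ± 12.6 to 127 ± 13.8 CPM (-0.63 ± 0.07, edgeR adjusted p = 4.56e-05). SIFa, the gene of a feeding and sleep peptide, fell from 19.8 ± 2.04 to 10.2 ± 1.32 CPM (-0.96 ± 0.10, edgeR adjusted p = 2.89e-05) and Mip fell (-0.53 ± 0.07, edgeR adjusted p = 9.74e-05). Of the list of insulin-like peptides and feeding neuropeptides, 1 rose and 16 fell of 31, or 1 and 17 adjusted over the list alone (camera adjusted p = 1.04e-04, 0.783 with an estimated correlation between genes). Of the synaptic transmission list, 0 rose and 24 fell of 37, or 0 and 26 adjusted over the list alone (camera adjusted p = 2.95e-05, 0.783 estimated). Its members include Rbp, of the active zone, which fell from 811 ± 33.3 to 560.1 ± 28.1 CPM (-0.53 ± 0.05, edgeR adjusted p = 7.79e-06), and the potassium channel gene slo, which fell from 1252 ± 23.9 to 969 ± 21.5 CPM (-0.37 ± 0.04, edgeR adjusted p = 5.60e-05). VGlut (-0.33 ± 0.04, edgeR adjusted p = 8.41e-05) and nSyb (-0.34 ± 0.05, edgeR adjusted p = 2.28e-04), of vesicle filling and fusion, fell as well. Of the RNA granule list, 1 rose and 12 fell of 29, or 1 and 13 adjusted over the list alone (camera adjusted p = 0.00627, 0.783 estimated), among them tral (-0.25 ± 0.04, edgeR adjusted p = 2.35e-04), pum (-0.30 ± 0.04, edgeR adjusted p = 3.00e-04) and stau (-0.26 ± 0.04, edgeR adjusted p = 5.03e-04). These 3 were the lists called in this comparison, and none holds with an estimated correlation. The synaptic list had a median log2 fold change of -0.17. The muscle and fat body lists, which were not called, had medians of 1.26 and 0.98. Transcripts of gut enzymes shifted further, though few were called. The gut and salivary enzyme list, with 1 of 11 called, had a median of 6.04. The 4 tested Jonah proteases, with 0 called over all genes, had a median of 9.41. Whether a changed share of tissues contributed to the synaptic fall was not tested. Of the neuron list, 0 rose and 5 fell of 10. Of the glia list, 4 rose and 7 fell of 22. Of the activity-regulated list, 4 rose and 0 fell of 11. The glial gene axo fell from 397 ± 14.9 to 178 ± 19.2 CPM (-1.16 ± 0.07, edgeR adjusted p = 1.87e-07) and Mdr65, a transporter of the blood-brain barrier, rose from 137 ± 14.7 to 315 ± 43.7 CPM (1.204 ± 0.11, edgeR adjusted p = 1.66e-05). Of the nicotinic receptor list, 2 rose and 2 fell of 10, with nAChRalpha3 higher (1.38 ± 0.06, edgeR adjusted p = 1.64e-08).

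In the lipid and immune lists more genes rose than fell, though none of these lists was called, and in the lists of sugar metabolism more fell. InR, the insulin receptor gene, rose from 113 ± 3.33 to 233 ± 7.36 CPM (1.04 ± 0.07, edgeR adjusted p = 1.02e-06), FASN2, a fatty acid synthase, from 0.743 ± 0.139 to 11.1 ± 7.24 CPM (3.89 ± 0.53, edgeR adjusted p = 2.80e-04), and Hnf4, a lipid-sensing nuclear receptor, rose (0.84 ± 0.12, edgeR adjusted p = 3.00e-04). Of the lipid, starvation and nutrient signalling list, 10 rose and 2 fell of 33 (camera adjusted p = 0.08, so not called). AttA, an antimicrobial peptide gene, rose from 3.03 ± 0.919 to 15.5 ± 7.01 CPM (2.35 ± 0.36, edgeR adjusted p = 5.24e-04) and egr, a tumour necrosis factor, from 49.7 ± 3.97 to 122 ± 4.25 CPM (1.297 ± 0.07, edgeR adjusted p = 1.14e-07). Of the antimicrobial peptides, 7 rose and 0 fell of 27, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0645). Of the immune recognition and signalling list, 14 rose and 3 fell of 37 (camera adjusted p = 0.0979). Treh, which splits the blood sugar trehalose, fell from 826 ± 59.3 to 511 ± 70.2 CPM (-0.69 ± 0.09, edgeR adjusted p = 1.17e-04), and Pfk (-0.44 ± 0.05, edgeR adjusted p = 3.74e-05) and Tpi (-0.59 ± 0.08, edgeR adjusted p = 1.15e-04) of glycolysis fell. Ldh rose (1.29 ± 0.14, edgeR adjusted p = 3.13e-05). Of the glycogen and trehalose list, 1 rose and 3 fell of 14. Of glycolysis, 2 rose and 7 fell of 15. Of the pyruvate and citric acid cycle list, 2 rose and 6 fell of 20. Of the nuclear respiratory chain list, 2 rose and 6 fell of 43, or 1 and 4 adjusted over the list alone. Of the genes encoded in the mitochondrion, 0 rose and 0 fell of 13.

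**Figure D2:**
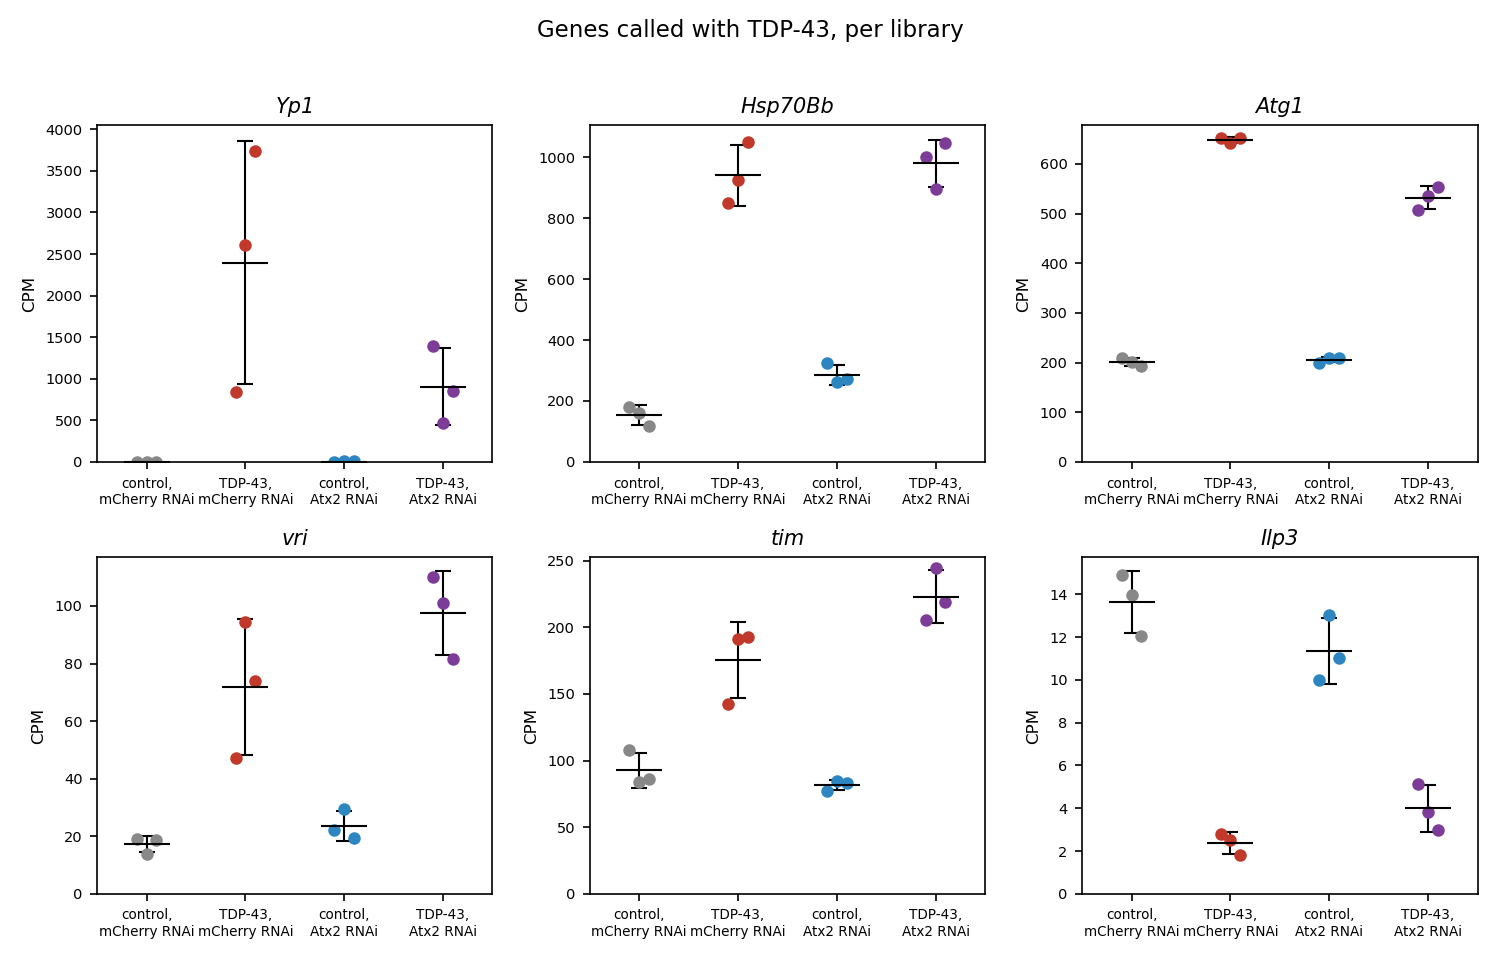
Level of Yp1, Hsp70Bb, Atg1, vri, tim and Ilp3 in CPM (vertical axes, from 0) in each library of the 4 groups (horizontal axes), with the mean ± SD (n = 3). Atg1 stood at 201 and 648 CPM without and with TDP-43 under mCherry RNAi, and at 206 and 532 CPM under Atx2 RNAi.

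Gene families and markers of other tissues changed in part. Given as members that rose and that fell, the detoxification families had 18 and 8 of 74 cytochrome P450 genes, 7 and 5 of 32 glutathione S-transferases and 11 and 3 of 24 UDP-glycosyltransferases. Secreted proteins had 5 and 4 of 26 (3 and 2 adjusted over the list alone) for odorant-binding proteins, 6 and 1 of 33 (5 and 1 adjusted over the list alone) for cuticular proteins and 5 and 1 of 17 for serpins. The cytoplasmic ribosomal proteins had 7 and 6 of 86 (6 and 5 adjusted over the list alone), the mitochondrial ones 3 and 4 of 72 (0 and 0 adjusted over the list alone), the vacuolar ATPase subunits 4 and 6 of 21 and the histones, which are near-identical copies, 0 and 2 of 4. Among tissue markers the counts were 8 and 4 of 24 (13 and 4 adjusted over the list alone) for muscle, 2 and 1 of 15 for hemocytes and 1 and 0 of 11 for gut and salivary enzymes. They were 0 and 0 of 4 (4 and 0 adjusted over the list alone) for the Jonah proteases of the gut and 1 and 0 of 4 (0 and 0 adjusted over the list alone) for the male reproductive tract. Act79B, a muscle actin, fell from 54.2 ± 3.17 to 16.8 ± 1.25 CPM (-1.69 ± 0.16, edgeR adjusted p = 1.62e-05) while Act57B, another, rose (2.03 ± 0.41, edgeR adjusted p = 0.00447). Of the photoreceptor list, 0 rose and 7 fell of 31, with a median of 0.09, a mean of 0.07 and a test pointing down (camera adjusted p = 0.0979). The rhodopsin ninaE, chosen after its values were seen, lay over 1000 CPM in replicate 2 of every group except the control with mCherry RNAi, at 1185, 1840 and 1135 CPM, so eye transcripts differed between libraries of a group. Median, mean and set test differed in sign in 7 of 37 lists here, and in 0 of the called ones.

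The second comparison asked what Atx2 knockdown changes in flies that express TDP-43, the setting of the rescue named in the series title. Each hairpin came from its own stock, so a difference between the stocks cannot be told apart from knockdown here. More genes rose than fell in the sleep and synaptic lists. Some genes of lipid metabolism, of detoxification and of the fat body fell. None of the lists called here holds with an estimated correlation between genes. By edgeR's test 1508 genes were called, 825 higher and 683 lower, with a median called change of 0.33, and 62 rose and 189 fell more than 2-fold. In 3508 genes, or 32.7%, the libraries did not overlap, where chance gives 10%. The count was 911 in the 6 libraries compared alone and 506 with the replicate number as a block there. With the block over all libraries it was 1718. The TDP-43 libraries with mCherry RNAi stood apart from one another. Their squared count differences, in units of counting noise per gene, were 188, 111 and 122 between pairs, against 18.4 to 68.4 within the other groups, and replicate 1 lay nearer to replicates 1 and 3 of TDP-43 with Atx2 RNAi (64.6 and 77.1). The count was 967 without replicate 3 of TDP-43 with mCherry RNAi, and 731 and 802 without replicates 2 and 3 of TDP-43 with Atx2 RNAi.

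The sleep and synaptic lists were the 2 called higher. Each had a median log2 fold change of 0.07, against -0.75 for muscle and -1.08 for the fat body, both called lower. Whether a changed share of tissues contributed was not tested. Of the sleep list, 10 rose and 2 fell of 44, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.00232, 0.662 with an estimated correlation), with Nlg4, a neuroligin gene, up from 121 ± 2.8 to 160.1 ± 4.39 CPM (0.40 ± 0.05, edgeR adjusted p = 4.43e-04). Of the synaptic transmission list, 9 rose and 2 fell of 37, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0364, 0.943 estimated), with the potassium channel genes Shab up from 876 ± 39.5 to 1102 ± 23.8 CPM (0.33 ± 0.05, edgeR adjusted p = 0.00138) and eag up (0.26 ± 0.04, edgeR adjusted p = 0.00287), and Rbp up from 560.1 ± 28.1 to 698 ± 15.1 CPM (0.32 ± 0.05, edgeR adjusted p = 0.00165). The cilium gene nompB rose from 2.42 ± 0.725 to 19.3 ± 1.9 CPM (edgeR adjusted p = 5.88e-06), Sec31, of vesicle coats, from 77.3 ± 6.16 to 149 ± 9.5 CPM (0.95 ± 0.06, edgeR adjusted p = 4.05e-06), ALiX, of endosomal sorting, from 77 ± 3.51 to 140.4 ± 3.62 CPM (0.87 ± 0.06, edgeR adjusted p = 5.34e-06), and the vesicular transporter gene prt from 20.6 ± 2.29 to 43.9 ± 2.43 CPM (1.09 ± 0.10, edgeR adjusted p = 4.37e-05). The glial gene axo and the cell adhesion gene bdl rose from 178 ± 19.2 to 296 ± 7.33 CPM (0.73 ± 0.07, edgeR adjusted p = 5.56e-05) and from 135 ± 16.6 to 252 ± 14.4 CPM (0.90 ± 0.08, edgeR adjusted p = 5.02e-05). Of the glia list, 2 rose and 2 fell of 22. The antisense genes asRNA:CR45822 and asRNA:CR45835, near 0 with TDP-43 and mCherry RNAi, stood at 7.9 ± 0.767 and 10.2 ± 1.18 CPM (edgeR adjusted p = 4.62e-09 and 7.61e-10). Of the photoreceptor list, 3 rose and 0 fell of 31, not called (camera adjusted p = 0.0509) but called with the replicate block (adjusted p = 0.0284). The 3 libraries highest in ninaE include 1 of each group compared here, and 332 genes were called without them.

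Lipid, detoxification and fat body lists were among the 10 called lower. Of the lipid, starvation and nutrient signalling list, 0 rose and 11 fell of 33, or 0 and 15 adjusted over the list alone (camera adjusted p = 2.25e-06, 0.662 with an estimated correlation). Pepck2, of gluconeogenesis, fell from 5.4 ± 0.605 to 0.689 ± 0.192 CPM (-2.96 ± 0.27, edgeR adjusted p = 5.19e-05), and InR from 233 ± 7.36 to 174 ± 15.8 CPM (-0.42 ± 0.07, edgeR adjusted p = 0.00318). Of the UDP-glycosyltransferases, 0 rose and 12 fell of 24, or 1 and 12 adjusted over the list alone (camera adjusted p = 2.10e-07, 0.475 estimated), with Ugt35B1 down from 193 ± 12.5 to 56.2 ± 2.04 CPM (-1.78 ± 0.05, edgeR adjusted p = 7.61e-10) and Ugt49C1 from 48.4 ± 13.1 to 14.3 ± 1.08 CPM (-1.75 ± 0.16, edgeR adjusted p = 1.04e-04). Of the cytochrome P450 genes, 2 rose and 17 fell of 74, or 5 and 21 adjusted over the list alone (camera adjusted p = 2.82e-04, 0.76 estimated), with Cyp12a4 down from 57.5 ± 5.19 to 24.1 ± 1.19 CPM (-1.25 ± 0.10, edgeR adjusted p = 2.86e-05) and Cyp28d1 from 567 ± 25 to 331 ± 11.6 CPM (-0.78 ± 0.07, edgeR adjusted p = 5.56e-05). Of the glutathione S-transferases, 1 rose and 7 fell of 32, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.00935, 0.76 estimated), among them GstD2, down from 4.64 ± 1.3 to 0.905 ± 0.0662 CPM (-2.35 ± 0.29, edgeR adjusted p = 4.49e-04). The antisense gene asRNA:CR45600 (3R, 15136985 to 15140121) fell from 88.4 ± 4.98 to 2.95 ± 0.183 CPM (-4.90 ± 0.08, edgeR adjusted p = 4.16e-12) and CG6912, which it overlaps, from 59.7 ± 8.33 to 2.8 ± 0.333 CPM (-4.42 ± 0.11, edgeR adjusted p = 5.32e-10).

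Some fat body transcripts fell, with different certainty. Of the fat body list, 0 rose and 3 fell of 20, or 0 and 4 adjusted over the list alone (camera adjusted p = 4.93e-04, 0.662 estimated). Obp99a fell from 57.1 ± 25.5 to 2.81 ± 1.45 CPM (-4.35 ± 0.46, edgeR adjusted p = 6.47e-04), though with the replicate block in the 6 libraries its edgeR adjusted p was 0.144. The glucosidase gene tobi fell from 41.2 ± 28.7 to 0.838 ± 0.121 CPM (-5.60 ± 0.84, edgeR adjusted p = 0.00379), and its edgeR adjusted p with that block was 0.0964. The storage protein gene Lsp2 fell from 30.9 ± 26 to 0.428 ± 0.257 CPM (-6.13 ± 1.17, edgeR adjusted p = 0.0112), with an edgeR adjusted p of 0.0602 without replicate 2 of TDP-43 with Atx2 RNAi. The fatty acid synthase gene FASN1 stood at 1160.0 ± 506 and 517 ± 33.7 CPM and the neuronal gene Arc1 at 134 ± 68 and 46.1 ± 15.9 CPM (edgeR adjusted p = 0.0425 and 0.0246, and 0.318 and 0.260 with the block). The call of FASN1 was lost without replicate 2 or 3 of TDP-43 with mCherry RNAi (edgeR adjusted p = 0.126 and 0.127) or replicate 1, 2 or 3 of TDP-43 with Atx2 RNAi (0.0924, 0.137 and 0.123). That of Arc1 was lost without replicate 2 or 3 of the latter group (edgeR adjusted p = 0.101 and 0.0954). Yp1 stood at 2398 ± 1458 and 906 ± 464 CPM and was not called (-1.40 ± 0.79, edgeR adjusted p = 0.288). Of the antimicrobial peptides, 0 rose and 3 fell of 27 (camera adjusted p = 8.61e-06, 0.662 estimated). Of the immune list, 1 rose and 5 fell of 37, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.0052, 0.806 estimated). Of the glycogen and trehalose list, 0 rose and 3 fell of 14, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.0155, 0.662 estimated). Of the serpins, 0 rose and 3 fell of 17 (camera adjusted p = 0.0453, 0.806 estimated). Of the muscle list, 1 rose and 1 fell of 24 (camera adjusted p = 0.00855, 0.835 estimated).

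**Figure D3:**
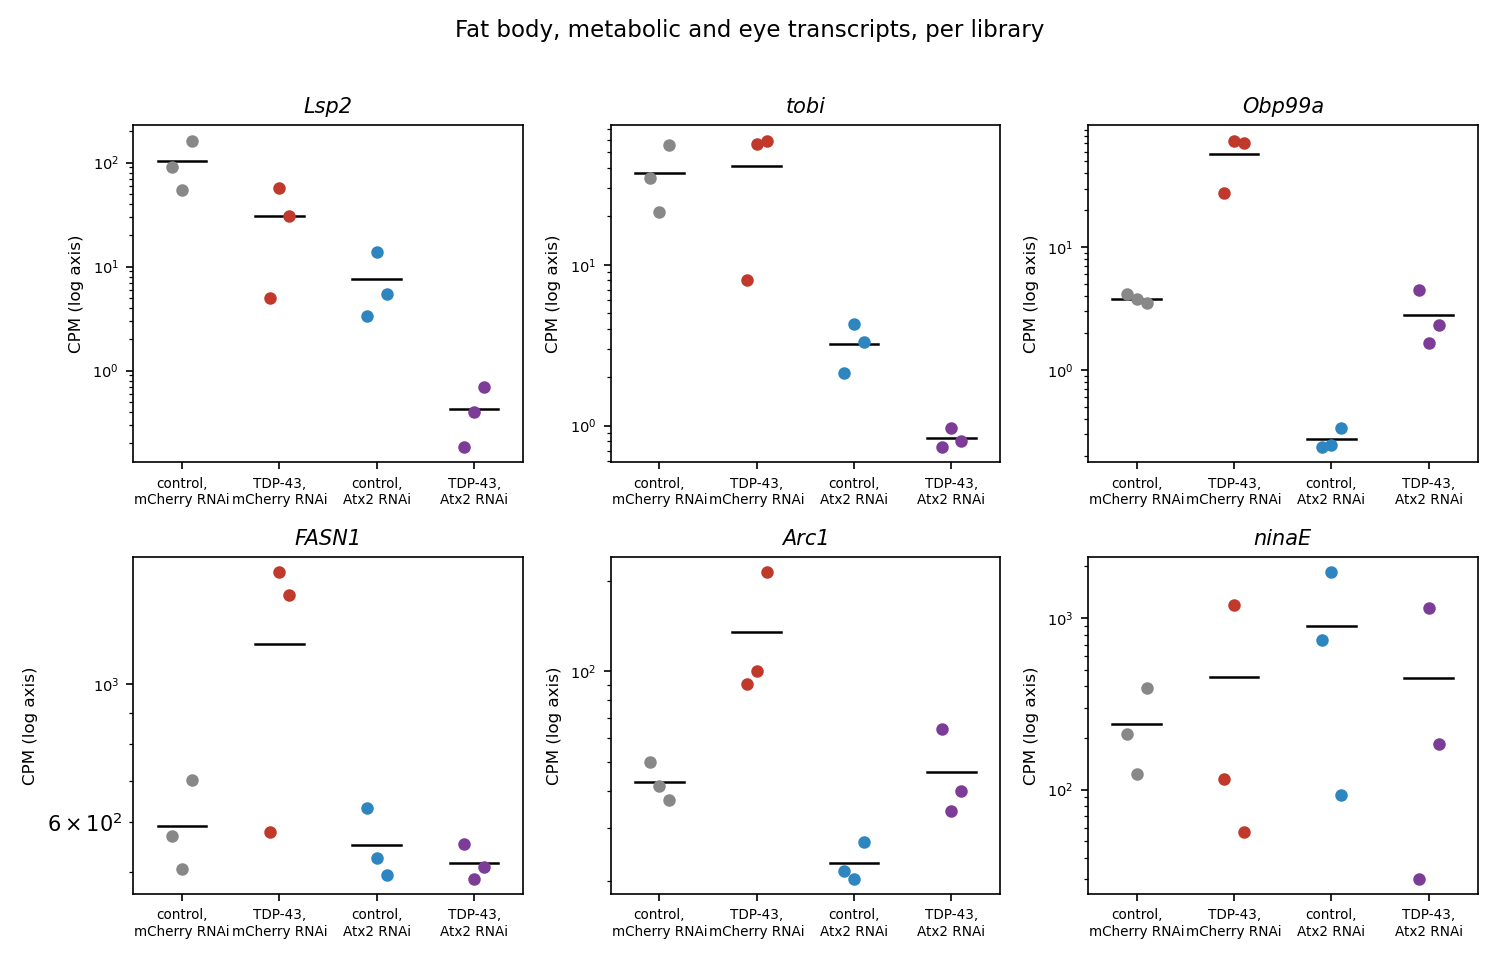
Level of Lsp2, tobi, Obp99a, FASN1, Arc1 and ninaE in CPM on log axes (vertical) in each library of the 4 groups (horizontal), with a line at the mean of each group. Obp99a stood at 57.1 CPM with TDP-43 and mCherry RNAi and at 2.81 CPM with TDP-43 and Atx2 RNAi, while ninaE varied within groups, up to 1840 CPM.

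Few neuropeptide genes were called. Ilp2, already lower with TDP-43, fell again from 127 ± 13.8 to 90.0 ± 3.98 CPM (-0.49 ± 0.07, edgeR adjusted p = 0.00136). Of the neuropeptide list, 1 rose and 1 fell of 31, or 0 and 1 adjusted over the list alone. Of the clock list, 4 rose and 2 fell of 18, with cry down from 53.5 ± 1.18 to 35 ± 0.916 CPM (-0.61 ± 0.07, edgeR adjusted p = 2.58e-04). Atg1 fell from 648 ± 6.21 to 532 ± 22.7 CPM (-0.29 ± 0.04, edgeR adjusted p = 0.0017) and ref(2)P, an autophagy receptor, from 251 ± 1.41 to 200.2 ± 5.71 CPM (-0.32 ± 0.04, edgeR adjusted p = 7.09e-04). Of the autophagy list, 0 rose and 3 fell of 25, or 0 and 2 adjusted over the list alone. Of the heat shock list, 1 rose and 1 fell of 22, or 1 and 0 adjusted over the list alone. Of the RNA granule list, 5 rose and 3 fell of 29. Mdh1, a malate dehydrogenase gene on the pyruvate and citric acid cycle list, fell from 193 ± 15 to 116 ± 3.68 CPM (-0.73 ± 0.11, edgeR adjusted p = 0.00222). Of that list, 0 rose and 4 fell of 20, or 1 and 4 adjusted over the list alone. Of the cytoplasmic ribosomal proteins, 2 rose and 0 fell of 86, or 0 and 0 adjusted over the list alone. The mitochondrial large ribosomal RNA held 5.39 to 5.54% of the counts in TDP-43 libraries with mCherry RNAi and 3.14 to 4.14% in those with Atx2 RNAi, though of the genes encoded in the mitochondrion 0 rose and 0 fell of 13.

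The third comparison asked what Atx2 knockdown changes in flies without TDP-43. Here too, a difference between the hairpin stocks cannot be told apart from knockdown. Of the 86 cytoplasmic ribosomal protein genes, 43 rose. The detoxification genes Ugt35B1, Cyp28d1 and Cyp12a4 and the storage protein gene Lsp1beta fell. By edgeR's test 663 genes were called, 348 higher and 315 lower, and the median called change was 0.38. Libraries did not overlap in 2760 genes, or 25.7%, where chance gives 10%. The count was 380 and 371 without control replicates 1 and 2 with mCherry RNAi, and 282, 432 and 327 without control replicates 1, 2 and 3 with Atx2 RNAi.

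None of the 16 lists called in this comparison holds with an estimated correlation, with adjusted p = 0.853 for the lists other than the respiratory chain (0.904) and the photoreceptors (0.866). Of the cytoplasmic ribosomal proteins, 43 rose and 0 fell of 86, or 72 and 0 adjusted over the list alone (camera adjusted p = 5.02e-37). RpS24 rose from 335 ± 22.5 to 471 ± 43.7 CPM (0.49 ± 0.07, edgeR adjusted p = 0.00169) and RpL32, a common reference gene, from 361 ± 13.6 to 534 ± 73 CPM (0.57 ± 0.08, edgeR adjusted p = 0.00242). Of the genes encoded in the mitochondrion, 3 rose and 0 fell of 13, or 8 and 0 adjusted over the list alone (camera adjusted p = 3.34e-05). Of the nuclear respiratory chain, 1 rose and 0 fell of 43, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.00359). Of the proteasome, 3 rose and 0 fell of 35, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0037). Of the photoreceptor list, 1 rose and 0 fell of 31 (camera adjusted p = 0.00828), and ninaE lay at 746 and 1840 CPM in control replicates 1 and 2 with Atx2 RNAi. As with TDP-43, nompB rose from 2.6 ± 0.478 to 22.6 ± 1.12 CPM (3.11 ± 0.20, edgeR adjusted p = 7.55e-06) and Sec31 from 79.4 ± 1.42 to 153 ± 2.16 CPM (0.95 ± 0.06, edgeR adjusted p = 6.61e-06). The DNA repair gene phr rose from 30.8 ± 2.37 to 59.1 ± 2.91 CPM (0.94 ± 0.08, edgeR adjusted p = 2.86e-05), as did Prosalpha1, which overlaps it (0.48 ± 0.06, edgeR adjusted p = 4.43e-04). Hsp70Bb rose from 153 ± 33.1 to 286 ± 33.5 CPM (0.90 ± 0.16, edgeR adjusted p = 0.00978).

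Among the falls, Ugt35B1 went from 362 ± 1.17 to 143 ± 3.79 CPM (-1.34 ± 0.05, edgeR adjusted p = 3.34e-08), Cyp28d1 from 532 ± 29.3 to 295 ± 30.9 CPM (-0.85 ± 0.07, edgeR adjusted p = 3.44e-05) and Cyp12a4 from 64.8 ± 7.9 to 28.4 ± 3.02 CPM (-1.19 ± 0.10, edgeR adjusted p = 4.29e-05). The lists called lower, given next, all had an adjusted p of 0.853 with an estimated correlation and so do not hold there. Of the cytochrome P450 genes, 2 rose and 9 fell of 74 (camera adjusted p = 9.06e-04), and the UDP-glycosyltransferases were also called lower (0.0193), where 2 rose and 3 fell of 24, or 3 and 9 adjusted over the list alone. Lsp1beta fell from 101 ± 47.7 to 5.07 ± 1.75 CPM (-4.33 ± 0.48, edgeR adjusted p = 0.00143) and Obp99a from 3.8 ± 0.316 to 0.272 ± 0.0551 CPM (-3.78 ± 0.55, edgeR adjusted p = 0.00491). Other lists called lower, given as members that rose and that fell with the camera adjusted p, were the fat body at 0 and 2 of 20 (0 and 3 adjusted over the list alone) (0.0345), odorant-binding proteins at 0 and 1 of 26 (0 and 2 adjusted over the list alone) (0.00651) and lipid signalling at 0 and 2 of 33 (0.0142). Of sugar metabolism, glycogen and trehalose stood at 0 and 3 of 14 (0 and 4 adjusted over the list alone) (9.06e-04), glycolysis at 0 and 2 of 15 (0.0316) and the citric acid cycle at 0 and 2 of 20 (0 and 4 adjusted over the list alone) (0.0321). Muscle stood at 0 and 2 of 24 (5.57e-04), glia at 0 and 2 of 22 (0 and 6 adjusted over the list alone) (0.0275) and activity-regulated genes at 0 and 0 of 11 (0.0345). Trh, which makes serotonin, fell from 50.5 ± 4.03 to 30.7 ± 1.33 CPM (-0.72 ± 0.09, edgeR adjusted p = 7.79e-04) and DAT, the dopamine transporter, from 40.1 ± 3.37 to 29.9 ± 0.533 CPM (-0.42 ± 0.08, edgeR adjusted p = 0.00897). Ilp2 fell from 196 ± 12.6 to 143 ± 3.38 CPM (-0.45 ± 0.07, edgeR adjusted p = 0.00339). Few of the sleep (1 and 1 of 44), clock (1 and 1 of 18), neuropeptide (0 and 1 of 31) and synaptic lists (1 and 3 of 37 (2 and 7 adjusted over the list alone)) were called. Against the second comparison, which shares no library with this one, 178 genes rose in both where independent lists would share 26.7, and 164 fell in both where they would share 20.04. Opposite signs occurred in 2 and 3 genes. A difference between the hairpin stocks would also be shared by both comparisons.

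The fourth comparison asked what TDP-43 changes when Atx2 is knocked down, in libraries not used in the first. The genes Yp1, Hsp70Bb, Atg1, vri and tim rose again, and SIFa, Ilp2 and Ilp3 fell again. Of the 86 ribosomal protein genes, whose list was not called with the mCherry hairpin (camera adjusted p = 0.934), 55 fell. By edgeR's test 2413 genes were called, 1294 higher and 1119 lower, with a median called change of 0.47, and 610 rose and 100 fell more than 2-fold. Libraries did not overlap in 4707 genes, or 43.8%, where chance gives 10%. Of the genes higher with TDP-43 in the first comparison, 1075 were higher here, where independent lists would share 249, and of those lower, 840 were lower, where they would share 205. Opposite signs occurred in 3 and 2 genes. A difference in genetic background between flies with and without the transgene would also be shared by both comparisons.

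Yp1 rose from 4.68 ± 3.7 to 906 ± 464 CPM (7.63 ± 1.06, edgeR adjusted p = 0.00122) and Yp3 from 5.81 ± 5.79 to 583 ± 312 CPM (6.69 ± 0.93, edgeR adjusted p = 0.00122), though with the replicate block in the 6 libraries their edgeR adjusted p was 0.0668 and 0.0771. The autophagy gene Atg1 rose from 206 ± 5.2 to 532 ± 22.7 CPM (1.37 ± 0.04, edgeR adjusted p = 2.00e-09) and Hsp70Bb from 286 ± 33.5 to 980.1 ± 77.3 CPM (1.78 ± 0.16, edgeR adjusted p = 3.65e-05). Clock genes vri and tim rose from 23.6 ± 5.18 to 97.5 ± 14.5 CPM (2.05 ± 0.27, edgeR adjusted p = 6.14e-04) and from 81.7 ± 3.79 to 223 ± 19.7 CPM (1.45 ± 0.13, edgeR adjusted p = 3.09e-05), per rose from 35.8 ± 3.51 to 61.4 ± 7.9 CPM (0.78 ± 0.13, edgeR adjusted p = 0.00116) and cry fell from 66.2 ± 1.47 to 35 ± 0.916 CPM (-0.92 ± 0.07, edgeR adjusted p = 2.33e-06). Of the clock list, 5 rose and 3 fell of 18, or 5 and 4 adjusted over the list alone. Dop2R rose from 92.5 ± 4.77 to 177 ± 4.94 CPM (0.94 ± 0.05, edgeR adjusted p = 7.54e-08) and Dop1R1 from 285 ± 21.7 to 533 ± 8.69 CPM (0.90 ± 0.09, edgeR adjusted p = 1.66e-05). Of the sleep list, 10 rose and 10 fell of 44, or 12 and 13 adjusted over the list alone. Of the neuropeptide list, 2 rose and 13 fell of 31, or 2 and 14 adjusted over the list alone (camera adjusted p = 6.84e-05, 0.851 with an estimated correlation), with SIFa down from 25.3 ± 1.4 to 11.6 ± 0.462 CPM (-1.13 ± 0.10, edgeR adjusted p = 1.16e-05), Capa from 171 ± 12.3 to 82.2 ± 9.73 CPM (-1.05 ± 0.14, edgeR adjusted p = 4.79e-04), Ilp2 from 143 ± 3.38 to 90.0 ± 3.98 CPM (-0.67 ± 0.07, edgeR adjusted p = 4.39e-05) and Ilp3 from 11.3 ± 1.54 to 3.99 ± 1.09 CPM (-1.51 ± 0.21, edgeR adjusted p = 2.76e-04). The receptor gene mthl8 again stood near 0, at 61.3 ± 0.62 CPM without and 0.0921 ± 0.0592 CPM with TDP-43.

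None of the 9 lists called in this comparison holds with an estimated correlation, with adjusted p = 0.851 for all except the respiratory chain (0.958). Of the cytoplasmic ribosomal proteins, 0 rose and 55 fell of 86, or 1 and 65 adjusted over the list alone (camera adjusted p = 3.10e-16), with RpS9 down from 453 ± 44.7 to 281 ± 16.6 CPM (-0.69 ± 0.07, edgeR adjusted p = 2.83e-05) and RpS15 from 820.4 ± 95.5 to 546 ± 20.1 CPM (-0.59 ± 0.08, edgeR adjusted p = 2.13e-04). This fall, the rise in the third comparison and the interaction of these genes all use the same 3 libraries of control flies with Atx2 RNAi, so a high level in that group alone would give all of them. Of the genes encoded in the mitochondrion, 0 rose and 5 fell of 13, or 0 and 7 adjusted over the list alone (camera adjusted p = 0.0024), with mt:ND4 down from 1072 ± 88.2 to 767 ± 84.6 CPM (-0.48 ± 0.09, edgeR adjusted p = 0.0029). The mitochondrial large ribosomal RNA held 4.11 to 5.10% of the counts in control and 3.14 to 4.14% in TDP-43 libraries with Atx2 RNAi, which overlap, and went the other way under mCherry RNAi, with 4.60 to 5.42% in control and 5.39 to 5.54% in TDP-43 libraries. Of the nuclear respiratory chain, 0 rose and 5 fell of 43 (camera adjusted p = 0.0235). Of the RNA granule list, 1 rose and 7 fell of 29 (camera adjusted p = 0.0272). Of the synaptic list, 1 rose and 7 fell of 37 (camera adjusted p = 0.027). Of the photoreceptors, 0 rose and 4 fell of 31 (camera adjusted p = 0.0203), and ninaE varied within both groups, at 746, 1840 and 93.5 CPM without and 30.4, 1135 and 183 CPM with TDP-43. Rises were called in the activity-regulated list, where 2 rose and 0 fell of 11 (camera adjusted p = 0.0235), and in the muscle list, where 3 rose and 2 fell of 24, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0103). With the replicate block, glycolysis was called lower (adjusted p = 0.0439 against 0.104) and the gut enzymes higher (0.0374 against 0.122). The gut enzymes, with 1 of 11 called over all genes, had a median log2 fold change of 3.18, and the Jonah proteases, with 0 of 4 called, one of 4.55. Of the lipid list, 5 rose and 1 fell of 33. Of the antimicrobial peptides, 2 rose and 0 fell of 27. Of the immune list, 5 rose and 1 fell of 37. Of the fat body list, 6 rose and 3 fell of 20, or 7 and 3 adjusted over the list alone. Of the heat shock list, 2 rose and 1 fell of 22, or 2 and 0 adjusted over the list alone.

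**Figure D4:**
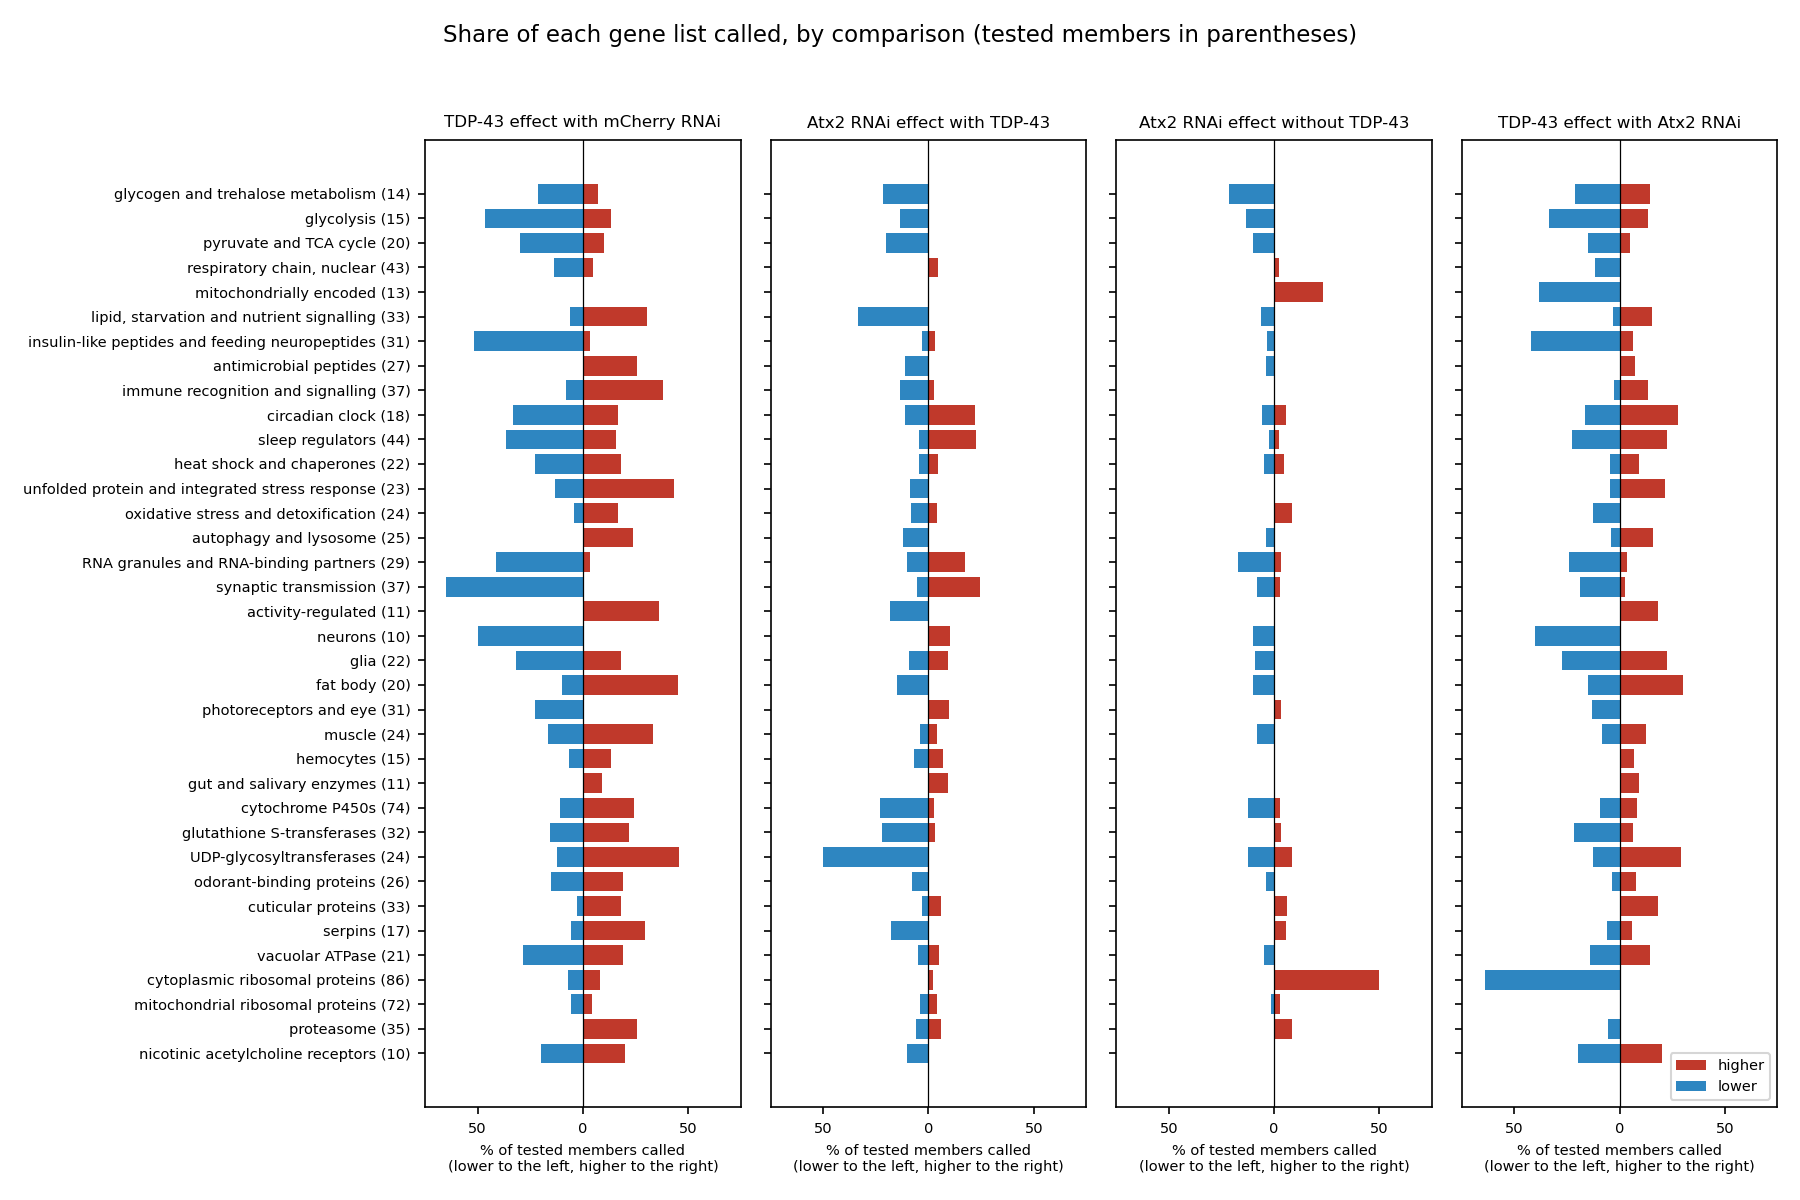
Percent of the tested members of each list with 10 or more tested genes that were called higher (bars to the right) or lower (bars to the left), with a panel for each of the first 4 comparisons. Of the cytoplasmic ribosomal proteins, 43 of 86 rose with Atx2 RNAi without TDP-43 and 55 of 86 fell with TDP-43 under Atx2 RNAi, and both counts use the same 3 libraries of control flies with Atx2 RNAi.

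The interaction asked whether the TDP-43 effect differs between the hairpins. Few single genes passed this test. They include a pair of neighbouring antisense genes, the glial gene axo and CG6912 with its antisense partner. By edgeR's test 46 genes were called, 28 with a TDP-43 effect more positive under Atx2 RNAi and 18 with one more negative, while 1636 had an unadjusted p under 0.05. The Wald test of DESeq2 called 507, among them only 30 of these 46. With the replicate number as a block 138 were called, among them all 46. The count was 18 and 15 without control replicates 1 and 2 with mCherry RNAi, 19, 26 and 19 without control replicates 1, 2 and 3 with Atx2 RNAi, and 10 and 11 without replicates 2 and 3 of TDP-43 with Atx2 RNAi.

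In the order control and TDP-43 with mCherry RNAi, then control and TDP-43 with Atx2 RNAi, asRNA:CR45822 stood at 8.78 ± 1.06, 0.0166 ± 0.0148, 15 ± 0.972 and 7.9 ± 0.767 CPM. The nearby asRNA:CR45835 stood at 12.7 ± 1.31, 0.0737 ± 0.0268, 22.1 ± 0.322 and 10.2 ± 1.18 CPM (edgeR adjusted p = 1.39e-07 and 4.15e-08). CG6912 (3R, 15135138 to 15137004) stood at 110.1 ± 5.56, 59.7 ± 8.33, 66.2 ± 2.18 and 2.8 ± 0.333 CPM (-3.69 ± 0.14, edgeR adjusted p = 4.39e-08) and asRNA:CR45600, which overlaps it, at 190.1 ± 14, 88.4 ± 4.98, 129 ± 5.92 and 2.95 ± 0.183 CPM (-4.34 ± 0.10, edgeR adjusted p = 2.32e-10). In CPM, these antisense genes and CG6912 fell with TDP-43 by amounts of similar size under both hairpins. The test compares ratios, so a low level in a TDP-43 group makes their interaction large. A stretch of chromosome that differs between the fly stocks may also underlie these levels. It could not be told apart from effects of TDP-43 or of the hairpins. The glial gene axo stood at 397 ± 14.9, 178 ± 19.2, 379 ± 8.81 and 296 ± 7.33 CPM (0.80 ± 0.09, edgeR adjusted p = 0.0039). The peptidase gene Nepl5 stood at 209 ± 26, 59.6 ± 1.63, 178 ± 4.59 and 103 ± 10.03 CPM (1.02 ± 0.12, edgeR adjusted p = 0.00419), the kinetochore gene Mis12 at 18.4 ± 1.36, 23.7 ± 2.52, 6.21 ± 0.358 and 16.7 ± 1.65 CPM (1.06 ± 0.14, edgeR adjusted p = 0.00953), the ecdysone-inducible gene ImpE1 at 34.3 ± 1.01, 32.8 ± 1.6, 31.8 ± 1.72 and 54.1 ± 6.15 CPM (0.83 ± 0.11, edgeR adjusted p = 0.00953) and CG8908 at 1.06 ± 0.255, 25.5 ± 8.13, 2.4 ± 0.161 and 7.81 ± 0.818 CPM (-2.88 ± 0.33, edgeR adjusted p = 0.0039). These 9 genes were called with each library left out in turn.

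Lists of genes were called where few single genes were, and none of these 12 lists holds with an estimated correlation (adjusted p = 0.704 for each). The TDP-43 effect under Atx2 RNAi was more negative for the cytoplasmic ribosomal proteins, with 0 of 86 called over all genes and 51 adjusted over the list alone (camera adjusted p = 5.07e-27). The same held for the genes encoded in the mitochondrion, with 0 of 13 and 7 adjusted over the list alone (camera adjusted p = 1.09e-04). It was also more negative for the UDP-glycosyltransferases (3.05e-05), the antimicrobial peptides (0.00114), the glutathione S-transferases (0.00253), the lipid list (0.00292), the proteasome (0.0195), the oxidative stress list (0.0196) and the serpins (0.0196). It was more positive for the synaptic list (1.07e-04), the sleep list (0.00172) and the glia list (0.00795). Of the sleep list 0 of 44 were called, or 6 higher and 1 lower adjusted over the list alone, and of the glia list 2 of 22, or 4. The immune list was called with the replicate block (adjusted p = 0.0482) and not without it (0.0551).

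Opposite calls count genes that changed one way with TDP-43 and the other way with Atx2 RNAi in TDP-43 flies. The glial gene axo, the cell adhesion gene bdl and the channel gene SLO2 fell with TDP-43 and rose with Atx2 RNAi. The glucose dehydrogenase gene Gld and the lipid phosphatase gene CG11425 rose and then fell. Of the genes called with TDP-43, 886 were called with the opposite sign with Atx2 RNAi in TDP-43 flies, or 21.96% of the first calls and 58.8% of the second. Of these, 341 rose and then fell and 545 fell and then rose, where independent lists would share 131 and 151, while 123 had the same sign in both comparisons. Without replicate 3 of TDP-43 with mCherry RNAi the count was 506, and without replicates 2 and 3 of TDP-43 with Atx2 RNAi it was 435 and 483. Both comparisons use the same TDP-43 libraries, whose noise enters them with opposite signs. Simulations with an equal TDP-43 effect under both hairpins gave a mean of 509 (470 to 545). The simulated libraries are independent of one another, without the possible pairing by replicate number in the data. They also have the same spread per gene in every group, though the TDP-43 libraries with mCherry RNAi differed more among themselves. The simulated ranges may thus be too narrow. With those 3 libraries divided so that the comparisons share none, in 6 ways, a single library stands for the group in one of the comparisons and the other groups supply its spread. In these divisions 164 to 615 genes were called with opposite signs and 40 to 135 with the same sign. Over all genes the covariance of the log2 fold changes then ran from -0.259 to 0.164.

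In control and TDP-43 flies with mCherry RNAi and then with Atx2 RNAi, bdl stood at 262 ± 9.82, 135 ± 16.6, 308 ± 16.1 and 252 ± 14.4 CPM (-0.96 ± 0.08 in the first comparison and 0.90 ± 0.08 in the second). SLO2 stood at 437 ± 15.3, 331 ± 3.72, 487 ± 21.9 and 450.3 ± 4.78 CPM (-0.40 ± 0.04, 0.45 ± 0.04) and axo at 397 ± 14.9, 178 ± 19.2, 379 ± 8.81 and 296 ± 7.33 CPM (-1.16 ± 0.07, 0.73 ± 0.07). Gld stood at 1.47 ± 0.292, 9.47 ± 4.11, 1.43 ± 0.0587 and 1.56 ± 0.0862 CPM (2.69 ± 0.28, -2.60 ± 0.28), and Dmtn at 149.7 ± 4.88, 242 ± 7.35, 137 ± 4.75 and 187 ± 1.42 CPM (0.69 ± 0.04, -0.37 ± 0.04). CG31688 stood at 218 ± 6.85, 799.5 ± 16.9, 211 ± 2.81 and 590.1 ± 33.5 CPM (1.88 ± 0.05, -0.44 ± 0.05). Without TDP-43, all libraries with Atx2 RNAi lay above those with mCherry RNAi for bdl and SLO2 and below them for Dmtn, though none was called (edgeR adjusted p = 0.121, 0.0503 and 0.0959). Of the 886 genes, 34 passed the interaction test, 351 were still called with TDP-43 under Atx2 RNAi in the first direction, and 101 were called with Atx2 RNAi without TDP-43.

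Across the genes called with TDP-43, the effect of TDP-43 under Atx2 RNAi was a median of 0.609 times that under mCherry RNAi. Simulations with equal effects gave 0.908 (0.892 to 0.920), since genes are picked by the first effect. These simulations lack the wider spread of the TDP-43 libraries with mCherry RNAi, so their ranges may be too narrow. The ratio was below 1, which includes genes whose effect changed sign, in 83.6% of the genes, against 62.6% in those simulations. With a single library left out the ratio ran from 0.533, without control replicate 3 with mCherry RNAi, to 0.634, without replicate 3 of TDP-43 with mCherry RNAi. Over all genes, the TDP-43 effects under the 2 hairpins correlated at r = 0.734 across genes, which are not independent replicates. The log2 fold changes of the first and second comparison had a covariance of -0.369, against -0.175 (-0.203 to -0.148) in simulations with equal effects and -0.0805 with no effects. Their correlation was -0.449, against -0.237 with equal effects and -0.490 with no effects, so it was no stronger than with no effects.

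**Figure D5:**
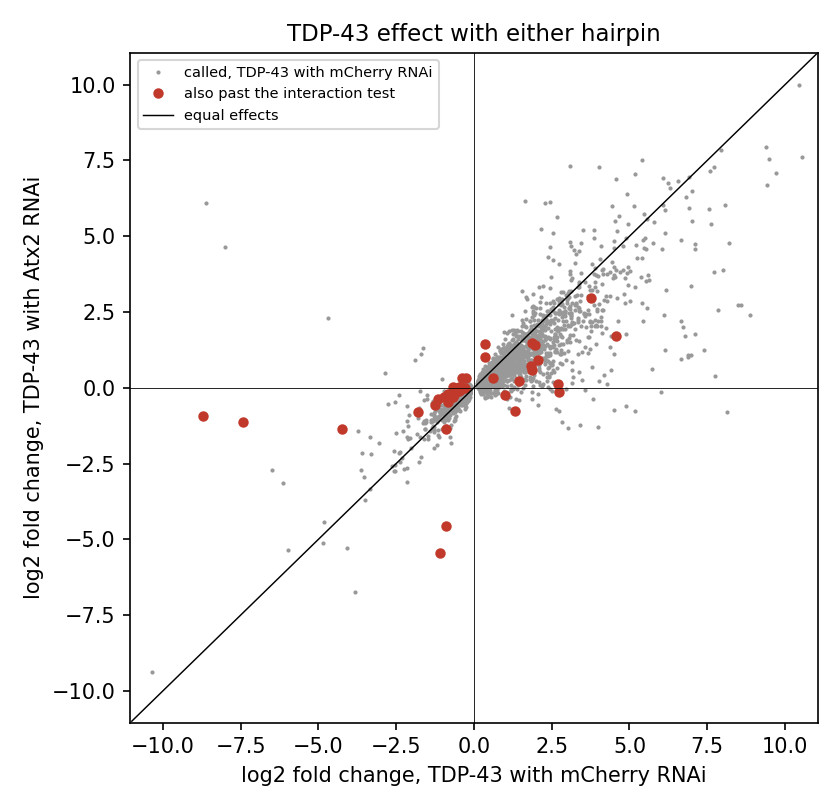
Log2 fold change with TDP-43 under mCherry RNAi (horizontal) and under Atx2 RNAi (vertical) of the 4035 genes called in the first comparison, a point per gene, with genes past the interaction test in red and a line of equal effects. The ratio of the vertical to the horizontal value was below 1 in 83.6% of these genes, with a median of 0.609.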

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

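The tests of the roX genes, of the other fat body genes, of chromosome stretches, of divided libraries, of the eye score and of fat tissue among opposite calls were chosen only after the results were seen.

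The TDP-43 effect differed between the hairpins on the log2 scale, by edgeR's interaction test, in 46 genes. The 17 of these named by the rule are given here. The log2 interaction was 7.79 for asRNA:CR45822 and 6.30 for asRNA:CR45835, fitted to groups near 0, so these sizes are no bounds. It was 1.06 for Mis12, 1.02 for Nepl5, 0.83 for ImpE1 and 0.80 for axo, and -4.34 for asRNA:CR45600, -3.69 for CG6912 and -2.88 for CG8908. These 9 were called with each library left out, with edgeR adjusted p up to 0.0494. The other 8 of the 17 depended on single libraries, and the genes not named are not judged here. GstD2 (-2.86) was not called without replicate 2 or 3 of TDP-43 with Atx2 RNAi (edgeR adjusted p = 0.0602 and 0.0533). The remaining 7 were asRNA:CR44291 (2.89), repo (0.60), Ugt35B1 (-0.44), Tsp42Ed (-1.14), Hsp67Ba (0.45), Ugt49C1 (-1.23) and spn-B (-0.78). Each of them lost its call without replicate 2 and without replicate 3 of TDP-43 with Atx2 RNAi and without replicate 1 of either control group, and the highest edgeR adjusted p were 0.0840, 0.0886, 0.110, 0.118, 0.171, 0.191 and 0.191. Other libraries mattered too: replicate 2 of control with mCherry RNAi for all 7, replicate 3 of control with Atx2 RNAi for all 7, and replicate 2 of that group for all except repo and Tsp42Ed. Replicate 1 of TDP-43 with Atx2 RNAi and replicate 2 of TDP-43 with mCherry RNAi mattered for Tsp42Ed, Hsp67Ba, Ugt49C1 and spn-B, and replicate 3 of TDP-43 with mCherry RNAi for Tsp42Ed, Hsp67Ba and spn-B. Replicate 3 of control with mCherry RNAi mattered for Ugt49C1 and spn-B, and replicate 1 of TDP-43 with mCherry RNAi for spn-B.

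The yolk protein genes and fit stood far higher with TDP-43 in flies labelled male. Female flies in the TDP-43 groups would bring roX1 and roX2, which male flies transcribe, to a log2 fold change of -0.42 or lower if they made up 25% of the flies. In TDP-43 flies with mCherry RNAi roX1 was at -0.088 ± 0.06 and roX2 at -0.12 ± 0.08, which argues against that share, while a smaller share may remain. In TDP-43 flies with Atx2 RNAi both were called lower. There roX1 was at -0.21 ± 0.06 (edgeR adjusted p = 0.0220), a fall too small for that share. But roX2, at -0.45 ± 0.08 (edgeR adjusted p = 0.00222), goes with it. A smaller share stays open there, or a larger one if roX1 rose for another reason. More fat tissue on the TDP-43 brains would raise other abundant fat body genes alike, but 10 of these had a median log2 fold change of 0.22, with 3 called higher and 2 lower, which argues against fat tissue as the whole cause; an effect of TDP-43 on these genes stays open and was not tested.

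Some genes stood at least 16-fold higher in every library of a group than in every library of another. With 5 CPM or more in the higher group, there were 20 such genes with TDP-43 under mCherry RNAi, 17 under Atx2 RNAi, 4 between the hairpins in TDP-43 flies and 0 between them in control flies. Stretches of chromosome that differ between the fly stocks may explain part of this: of 20 such genes, leaving out w, the yolk genes and fit, 4 lay within 50 kb of another, against a median of 0 and a highest of 6 in 10000 random sets (one-sided permutation p = 0.0201). The 4 are asRNA:CR45822 with asRNA:CR45835, near 0 in TDP-43 flies with mCherry RNAi, and CG6912 with asRNA:CR45600, which overlap and are low in TDP-43 flies with Atx2 RNAi, so shared reads between overlapping genes stay open for that pair. The other 16 have no such neighbour, and a TDP-43 effect on them stays open.

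The 886 opposite calls could come from noise in the TDP-43 libraries that both comparisons share. With those libraries divided so that none was shared, opposite signs made up 72.3% or more of the genes called in both, in each of 6 divisions. Each division leaves a single library for that group in one comparison, with the spread taken from the other groups, and in one of them the covariance of the fold changes over all genes was above 0, at 0.164. Simulations with equal effects, and with the same spread in every group, gave a mean of 509. Shared noise therefore stays open, as does a trait common to all 3 of those libraries. Simulations with a TDP-43 effect alone call almost no genes with Atx2 RNAi, so they decide nothing here. Eye tissue would remove the opposite calls when the eye-transcript score is a covariate, but 809 were called with it, 761 of them among the 886. Without the 3 libraries highest in ninaE 198 were opposite, and other ways to drop a library from each of the same groups gave 122 to 786. Fat tissue would give genes that rose and then fell, and 57.0% of the opposite calls, 505 genes, fell and then rose at over 20 CPM in control flies. Levels are relative, so more fat tissue could also lower brain transcripts. This count therefore cannot decide whether fat tissue contributed. An effect of Atx2 RNAi on transcripts changed by TDP-43 stays open, as does a difference between the stocks that carry the hairpins.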

How the results depend on the processing

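The eye-score covariate, leaving out the 3 libraries highest in ninaE, the replicate block within 6 libraries and the divided TDP-43 libraries were chosen only after the results were seen. No named gene reversed its direction where it was called. The balance of rises and falls did turn. Atx2 RNAi without TDP-43 gave 348 rises and 315 falls, but 323 and 341 with relative log expression scaling, 442 and 507 with the Wald test of DESeq2, 247 and 266 in the 6 libraries compared, and 193 and 290 without control replicate 3 with mCherry RNAi. TDP-43 with mCherry RNAi gave 2067 and 1968, but 2030 and 2075 with the other scaling and 1680 and 2001 without replicate 2 of its TDP-43 libraries. Atx2 RNAi with TDP-43 gave 825 and 683, but 32 and 49 against a fold of 1.5 and 247 and 259 with the block in 6 libraries. The interaction gave 28 and 18, but 28 and 37 without replicate 1 of TDP-43 with mCherry RNAi. The balance over all called genes is no finding in these comparisons. Among larger changes with TDP-43 under mCherry RNAi rises were the more frequent, at 629 and 129 against a fold of 1.5.

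Against a fold of 1.5 the counts were 758, 81, 59, 455 and 6 in the 5 comparisons in order and 26 opposite calls, which follows from a stricter question. Fewer libraries moved the counts both ways. With only the 6 libraries compared, Atx2 RNAi in TDP-43 flies gave 911 and TDP-43 under Atx2 RNAi 2782. Without the 3 libraries highest in ninaE, the comparisons after the first gave 332, 272, 1203 and 5, and 198 calls were opposite. Other ways to drop a library from each of the same 3 groups gave 251 to 1215 in the second comparison, 174 to 442 in the third, 1068 to 1633 in the fourth and 122 to 786 opposite calls. With a single library left out the counts ran from 3205 to 4261, 731 to 1664, 282 to 483, 1616 to 1813 and 10 to 68, and opposite calls from 435 to 1041. The Wald test of DESeq2 called 507 interaction genes; the cause was not tested.

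The replicate block gave 138 interaction genes, and 506 genes for Atx2 RNAi in TDP-43 flies within the 6 libraries compared, where the block over all libraries gave 1718; the cause was not tested. It gave 3372 within the 6 libraries of the fourth comparison, where the numbers also pair. In the first comparison same-numbered libraries correlated at 0.0514, -0.101 and 0.340, and in the third at -0.149, -0.100 and -0.333, so they share a number only. There the block gave 4258 and 712 genes, called the neuron (adjusted p = 0.0401) and gut lists (0.0401) in the first, and no longer called the activity-regulated list (0.0535) in the third. The block changed no other list call beyond those given beside their results. Of the 499 results for named genes, 16 lost their call with the block over all libraries. With the block in the 6 libraries compared, which covers only the second and the fourth comparison, 72 lost their call, 2 gained it and 177 did not change.

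With an estimated correlation 0 lists were called in each comparison. With fry, which asks only whether a list moves on balance, 15, 7, 3 and 11 lists were called in the first 4 comparisons and 0 in the interaction, and by its mixed test 36, 30, 29, 33 and 10. With the block 5 lists were called in the first comparison. The cause was not tested.

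Other counts stayed within 1.5 times. Relative log expression scaling gave 4105, 1470, 664, 2358 and 40 genes, no low-count filter 3861, 1252, 566, 2105 and 47, and 1 surrogate variable 3644, 1367, 567, 2307 and 36. No called list changed the sign of its median with the other scaling. Of the named gene results, 9 lost their call with the other scaling and 41 without the filter. Depth limits genes near 3 counts per library, where no fold is given.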

Other observations

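Beyond the genes named by the rule, several chosen after their values were seen differed between TDP-43 and control flies under both hairpins. NimA (2L, 13957539 to 13963381), of a phagocytosis receptor family, stood at 0.868 ± 0.177, 62 ± 10.3, 1.09 ± 0.109 and 63.8 ± 5.27 CPM in control and TDP-43 flies with mCherry RNAi and then with Atx2 RNAi. Cht2 (3L, 1752328 to 1755934), a chitinase gene, stood at 0.438 ± 0.171, 52.5 ± 9.46, 0.418 ± 0.036 and 51.9 ± 4.79 CPM. The ciliary genes IFT54 (3R, 14302428 to 14304458) and Root (3R, 24113286 to 24128193) stood at 0.144 ± 0.17, 11.9 ± 1.31, 0.104 ± 0.0907 and 10.7 ± 1.22 CPM and at 1.2 ± 0.776, 20.9 ± 0.792, 0.873 ± 0.0884 and 22.3 ± 2.7 CPM. CG9377 (2L, 13359901 to 13361565) went the other way, at 26.4 ± 6.79, 0.936 ± 0.839, 52.3 ± 11.4 and 1.51 ± 0.638 CPM.

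Fat body genes chosen after their values were seen moved apart. Lsp2 stood at 103 ± 55.2, 30.9 ± 26, 7.52 ± 5.52 and 0.428 ± 0.257 CPM, fon, of the clotting system, at 30.6 ± 16.4, 118 ± 48.5, 28.5 ± 15.1 and 42.5 ± 22.2 CPM, and Apoltp, a lipid transfer particle, at 157 ± 32.9, 167 ± 70.0, 119 ± 17.3 and 114 ± 24.3 CPM. The clock output gene to stood at 5.7 ± 2.22, 31.9 ± 28.5, 3.1 ± 4.71 and 29 ± 33.9 CPM. The driver gene da stood at 125 ± 2.26, 114 ± 5.03, 132 ± 1.52 and 124 ± 3.01 CPM.

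Splits of the 6 libraries of a comparison into other groups of 3 were planned. There are 10 splits, too few for a share under 0.05. The real split called 2853 genes in the first comparison and the highest other 16, and in the second 911 and 1, in the third 513 and 0, and in the fourth 2782 and 0. In each of these, 1 of the 10 splits, the real one, called as many. For Atx2 RNAi with TDP-43 and TDP-43 with Atx2 RNAi, 4 splits part all same-numbered pairs, as the real one does, and the highest other of these called 0. For the interaction, 8 of 100 splits drawn called at least the 46 genes of the real one, so this count cannot exclude a chance result. It is no fair measure of chance either. All 7 others keep the TDP-43 libraries with mCherry RNAi together and exchange hairpin labels among the control libraries, so they count the Atx2 RNAi effect common to both. The highest of them called 1845, several times the real count, which points to this structure of the samples. Among the splits that divide those TDP-43 libraries the highest called 8, though mixed groups also widen the spread.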
